A study of Mus musculus with 6 samples.

How the data were processed

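Open chromatin of mouse embryonic fibroblasts was measured by ATAC-seq in 3 wild-type and 3 FOP mutant libraries. Per the labels' protocols, nuclei were tagmented with a commercial kit, amplified by PCR and sequenced as paired-end reads. Whether the libraries of a genotype came from separate embryos is not said in the labels. The deposited data used here are a pair of region lists, 1 per direction, with a chromosome, a start and an end per region and no header. Their unit is the base pair position; they hold no read count, signal, fold change, p-value or value per library. Per the submitters' processing notes, the genome builds were mm10 and GRCm38, and Trimmomatic, Bowtie2, SAMtools, MACS2, bedtools, featureCounts and DESeq2 were used by the authors. Versions, parameters, the cutoff of the lists, the treatment of the transposase offset and duplicates, and whether peaks were called per library or on pooled libraries are not given in the sources used here. The direction of each list was taken from its name, since the files have no column for it. The order of the regions within a list is not genomic and was not used.

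These limits shape what could be measured. The lists hold what passed the authors' test, so peaks that did not change, the total number of peaks tested and the size of each change are not analysed here. Depth per library is unknown, and a difference in depth or signal between genotypes cannot be seen. All counts below describe the lists, with intervals that cover counting error only, and no p-value measures the spread between replicates.

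Gene positions came from the RefSeq gene table of GRCm38.p6, the build named in the processing notes, with 21883 protein-coding genes on chromosomes 1 to 19, X and Y. The table gives the start and end of each gene but no strand, exons or sequence, which led to departures from the design set before the data were examined. Each region was linked, by its midpoint, to the protein-coding gene whose span holds it or else to the nearest span within 100 kb, in place of the nearest transcription start. The planned promoter class became a class within 1 kb of either gene end, and the planned exon and intron classes became inside a gene and between genes. The length of a chromosome was taken as the extent from its first to its last annotated gene. Motif and GC content results were planned and were not run, as no sequence was used here. As a check of the build, all positions were shifted by 10 offsets and the share near gene ends was compared with the unshifted share.

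The share of more accessible regions was tested with an exact binomial test and given with a Clopper-Pearson 95% interval. Widths and log10 distances were compared by two-sided permutation tests with 100000 resamples. Chromosomes, annotation classes and gene lists were compared between directions by two-sided Fisher exact tests with Benjamini-Hochberg adjustment within each family. The 21 gene lists (603 symbols, all matched, 5 of them through a synonym; 583 different genes, 15 of them in more than 1 list) were fixed before the data were examined. For each direction the regions linked to a list were set against 10000 sets of random positions matched on chromosome, on lying inside or outside a gene and on distance to the nearest gene end (bins with edges at 1, 5, 20, 50 and 100 kb), drawn from a grid of 500 bp. Random positions were points, so region width was not matched. The smallest two-sided p of these sets is 0.0002. The annotation classes and the genes with several regions used 1000 sets. Regions per gene were tested against the matched expectation with a Poisson model over 21627 genes on chromosomes 1 to 19 and X, with Benjamini-Hochberg adjustment and a threshold of 0.05 throughout. The number of regions within 5 Mb of Acvr1 was ranked among autosomal windows of 10 Mb in steps of 1 Mb.

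The genes named in the text follow a rule set before the data were examined. For each direction these are the 10 genes linked to the most regions, up to 4 members with linked regions of each list, list genes with a region near a gene end, and Acvr1; other genes are said to be chosen after their values were seen. Some genes that the rule takes are not reported here. The tests were checked on simulated data with known answers. With no list changed, 1 of 2100 list tests at the size of each direction was called. Those sets were independent random positions drawn as in the test itself. They do not cover false calls from regions that lie close together, as the listed regions do. Lists with a 3-fold excess were found in 75% of cases at the size of the more accessible list and 11.25% at that of the less accessible list, and with a 2-fold excess in 17.5% and 2.5%. The 3-fold excess was planted in the matrix, WNT, actin and neural lists. In the same runs the 2-fold excess was planted in the positional and epithelial lists. These shares therefore mix fold with the list planted and do not hold for every list. Adjustment was within a direction, on fewer random sets than in the main test. Genes given 4 extra regions, 200 genes at once, were found in 91.5% and 99.5% of cases. With 200 changed genes the adjusted threshold is easier to pass than with few, so a single gene with such an excess can fail.

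Alternatives were other link distances, all annotated genes, merged neighbouring regions, autosomes alone, other limits near gene ends, random positions matched on chromosome alone and each linked gene counted once. Linking by the nearest gene end and leaving out the gene with the most regions of a list or family were added after the data were seen. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and bedtools 2.31.1.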

Results

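Chromatin accessibility was profiled by ATAC-seq, in which a transposase cuts and tags open DNA, in mouse embryonic fibroblasts. The 3 wild-type libraries carried 2 normal copies of Acvr1, which encodes the BMP type I receptor ALK2, and the 3 mutant libraries were heterozygous for the activating receptor mutation of fibrodysplasia ossificans progressiva (FOP). FOP is a disorder in which bone forms in muscle, tendon and other soft tissue. The question was which open chromatin regions differ between mutant and wild-type fibroblasts. The authors' deposited lists give the position of each differential region and, through the name of each list, its direction in mutant cells. They hold no read count, fold change or p-value per region, so the depth of each library is unknown here, and no difference could be set against the spread between replicates.

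The differential regions were mostly more accessible in mutant cells. The authors listed 2965 regions as more accessible and 556 as less accessible, so that 84.2% of 3521 regions gained accessibility (exact 95% interval 83.0 to 85.4%), a ratio of 5.33. The share lay far from an even split (two-sided exact binomial test, base-10 logarithm of p of -394), although neighbouring regions are not independent and regions are not replicates. The lists covered 1.83 Mb and 0.370 Mb of the genome. More accessible regions were slightly narrower, at 619 ± 242 bp (SD over 2965 regions) against 665 ± 248 bp (SD over 556 regions), a difference of -45.9 bp (two-sided permutation test, p = 8e-05). No region of either list overlapped a region of the other.

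Gene-rich chromosomes carried a larger share of less accessible regions. On chromosome 7, 28.7% of the 157 regions were less accessible (two-sided Fisher exact test, adjusted p = 0.00054), on chromosome 4 24.9% of 257 (adjusted p = 0.00083) and on chromosome 11 22.9% of 175 (adjusted p = 0.046). With regions within 10 kb merged, chromosome 11 did not pass (22.9%, Fisher exact test, adjusted p = 0.066). Chromosomes 7 and 11 have 14.0 and 13.2 protein-coding genes per Mb, but chromosome 4 only 8.49. The gene-dense chromosomes 19 (12.1 per Mb) and 17 (11.2 per Mb) did not pass, with shares of 18.6% and 22.0%. The share was low on chromosomes 3 (8.41% of 226, adjusted p = 0.0050), 10 (7.77%, adjusted p = 0.0040) and 16 (6.83% of 161, adjusted p = 0.0040). Over the 19 autosomes this share rose with the number of protein-coding genes per Mb (Pearson's r = 0.72, permutation p = 0.00080; Spearman's rho = 0.72, permutation p = 0.00055). Without chromosomes 7 and 11, the farthest from the median gene density, r was 0.54 (permutation p = 0.028). The X chromosome held 32 regions, 29 more and 3 less accessible. That is 0.909% of all regions (exact 95% interval 0.622 to 1.28%), while X makes up 6.53% of the annotated genome. Its density of 0.187 regions per Mb compares with 1.43 on the autosomes together and 1.07 on the autosome with the fewest per Mb. No listed region lay on chromosome Y. The sex of the embryos and any filter on the sex chromosomes are not given in the sources used here.

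**Figure D1:**
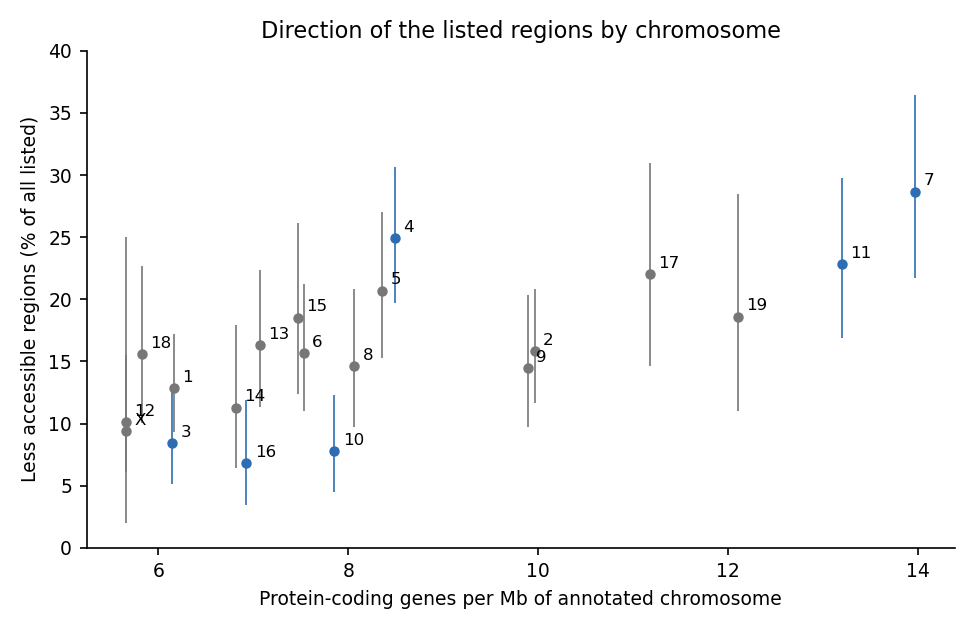
Share of less accessible regions among all listed regions of each chromosome (y axis, percent, with exact 95% binomial intervals) against protein-coding genes per Mb of annotated chromosome (x axis). Blue points are the 6 chromosomes that passed the Fisher exact test after adjustment (chromosome 11 not with regions within 10 kb merged), grey points the others; chromosome 7 has the highest share, 28.7%, and chromosome 16 the lowest, 6.83%.

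More accessible regions lay away from gene ends, and less accessible regions closer to them. The midpoint of 32 more accessible regions (1.08%, exact 95% interval 0.739 to 1.52%) was within 1 kb of an end of a protein-coding gene, against 20 less accessible regions (3.60%, 2.21 to 5.50%). The odds ratio was 0.29 (two-sided Fisher exact test, adjusted p = 0.00017). Random positions on the same chromosomes gave 2.97% for the more accessible set (2.36 to 3.61% in 95% of 1000 sets, n = 2965 regions, p = 0.0020, the smallest they can give) and 3.22% for the less accessible set (n = 556 regions, p = 0.65). Among the regions near an end were those at Fzd4, a WNT receptor, and Tnfaip3, an inhibitor of NF-kB signalling, in the more accessible list. In the less accessible list was that at Ptgs2, which encodes cyclooxygenase-2. The median distance to the nearest gene end was 56.0 kb for more accessible regions (random 51.0 kb, 46.5 to 56.1) and 24.0 kb for less accessible regions (random 46.9 kb, 38.0 to 57.9). The mean log10 distance differed by 0.33 (two-sided permutation test, p = 2e-05, the smallest it can give). Inside genes lay 44.7% of more and 45.0% of less accessible regions (two-sided Fisher exact test, adjusted p = 0.93). Both shares exceeded those of the random sets, 38.4% (n = 2965 regions, p = 0.0020) and 39.1% (n = 556 regions, p = 0.0060). Gene ends here are both the start and the end of transcription, because the annotation used gives no strand. With a limit of 500 bp the odds ratio was 0.40 and the difference did not pass the threshold (adjusted p = 0.11).

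**Figure D2:**
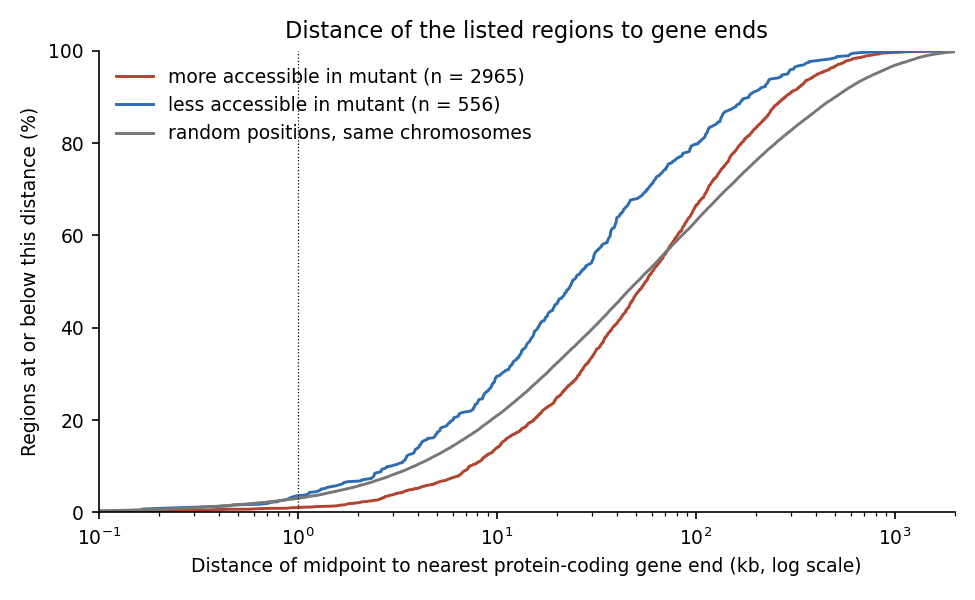
Cumulative share of regions (y axis, percent) by distance of the region's midpoint to the nearest end of a protein-coding gene (x axis, kb, log scale), for the 2965 more accessible regions, the 556 less accessible regions and random positions on the chromosomes of the more accessible regions. The dotted line marks 1 kb; the less accessible curve reaches its median at 24.0 kb and the more accessible curve at 56.0 kb.

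Genes of the extracellular matrix, of the actin cytoskeleton and cell adhesion, and of the WNT pathway were linked to more regions that gained accessibility than random regions would be. The 51 matrix genes had 28 such regions against 9.90 in random sets (2.83-fold, adjusted p = 0.0042), spread over 16 genes. Fbn1 and Fbn2, which encode fibrillins of the microfibrils, had 4 regions each, and the collagen genes Col8a1 and Col14a1 had 3 each. The 52 actin, adhesion and mechanosensing genes had 33 regions against 13.2 (2.51-fold, adjusted p = 0.0042) at 12 genes. They were led by Itga11, a collagen-binding integrin subunit, with 7 regions, Mylk, the myosin light chain kinase, with 5, and the integrin gene Itga8 and the mechanically gated channel gene Piezo2 with 3 each. The 43 WNT genes had 21 regions against 8.01 (2.62-fold, adjusted p = 0.0056) at 12 genes, among them Ror2, a WNT receptor, with 5, Tcf7l2, a transcription factor of the pathway, with 3, and Ccn4 and Tcf7l1 with 2 each.

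The p-values come from 10000 sets of random positions matched on chromosome and distance to genes, adjusted over 21 lists and both directions. Random positions are not the set of peaks that could have been called, so these folds are not relative to open chromatin. With each linked gene counted once no list passed: the folds were 1.85 for matrix genes (adjusted p = 0.26), 1.20 for actin genes (adjusted p = 1) and 1.74 for WNT genes (adjusted p = 0.39), and with links limited to 10 kb the actin list did not pass (1.84-fold, adjusted p = 0.16).

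Genes of bone formation and of BMP signalling had more linked regions than the random mean without passing the adjusted threshold. Osteogenic genes had 11 more accessible regions against 4.02 (2.74-fold, adjusted p = 0.071), among them 3 at Zfp521, a zinc finger regulator of osteoblasts, 2 at Runx2, the master transcription factor of the osteoblast lineage, and 1 at Tnfsf11, which encodes RANKL. BMP and TGF-beta ligands, receptors and SMADs had 14 against 6.67 (2.10-fold, adjusted p = 0.15), with 3 at Ltbp1, 2 at Bmp5 and 1 each at Bmpr2 and Ltbp2. BMP-SMAD target and feedback genes had 9 against 4.13 (2.18-fold, adjusted p = 0.20), with 3 at Bmper, a secreted BMP modulator, 2 at Msx2 and 1 each at Id3 and Atoh8. With regions linked to the nearest gene at any distance, osteogenic genes (3.34-fold, adjusted p = 0.0034) and the ligand and receptor genes (1.96-fold, adjusted p = 0.031) passed. Osteogenic genes also passed with random positions matched on chromosome alone (3.31-fold, adjusted p = 0.029) and with links by the nearest gene end (3.06-fold, adjusted p = 0.025), but not with links within 10 kb (2.23-fold, adjusted p = 0.53). With each gene counted once neither list passed (2.43-fold, adjusted p = 0.26, and 1.91-fold, adjusted p = 0.39). Less accessible regions gave 2.26-fold for osteogenic genes, 1.45-fold for ligands, receptors and SMADs and 2.65-fold for BMP-SMAD targets, on 2 regions each. The odds ratios of more to less accessible were 0.86, 1.09 and 0.71. An excess particular to more accessible regions was therefore not shown for these lists. Acvr1 itself (chromosome 2, 58446438 to 58566828, GRCm38) had no linked region. The nearest listed regions, both more accessible, lay 597 kb and 914 kb from it. Within 5 Mb of the gene there were 17 regions, 14 more and 3 less accessible, at the 61.7th percentile of 2260 autosomal windows of the same width (median 14).

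Positional identity genes, transcription factors that mark body regions, had 16 more accessible regions against 7.55 (2.12-fold, adjusted p = 0.084), including 4 at Tbx4, a hindlimb regulator, and 2 each at Prrx1, Tbx15 and Twist2. Inflammatory and interferon genes had 7 against 2.63 (adjusted p = 0.19), 2 of them at the chemokine gene Cxcl12 and 1 each at Il1r1, Tnfaip3 and Ccl7. With links at any distance the positional (1.95-fold, adjusted p = 0.027) and inflammatory genes (3.93-fold, adjusted p = 0.0034) passed, and with each gene counted once they did not (1.48-fold, adjusted p = 0.83, and 2.49-fold, adjusted p = 0.39). Tendon and joint genes had 6 against 2.20 (adjusted p = 0.20), 2 each at Erg and Osr1. Hedgehog, FGF and Notch pathway genes had 12 against 6.34 (adjusted p = 0.21), 4 of them at Gli3 and 2 at Fgf2. YAP/TAZ-TEAD genes had 7 against 5.55, 2 of them at Dlc1, chondrogenic genes 4 against 5.21, 2 of them at Hapln1, AP-1 and immediate early genes 1 (Klf4) against 2.19, and cell cycle and senescence genes 1 (Ccnd2) against 1.50 (adjusted p = 1 each). No list of markers of other cell types passed. The counts were 3 against 2.36 for skeletal muscle, 3 against 2.71 for endothelium, 1 against 1.98 for blood and macrophages, 2 against 1.87 for epithelium, 2 against 3.58 for adipogenic cells and 1 against 1.17 for smooth muscle and pericytes (adjusted p = 1 each). Neural and glial markers had 0 against 2.62 (adjusted p = 0.40).

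**Figure D3:**
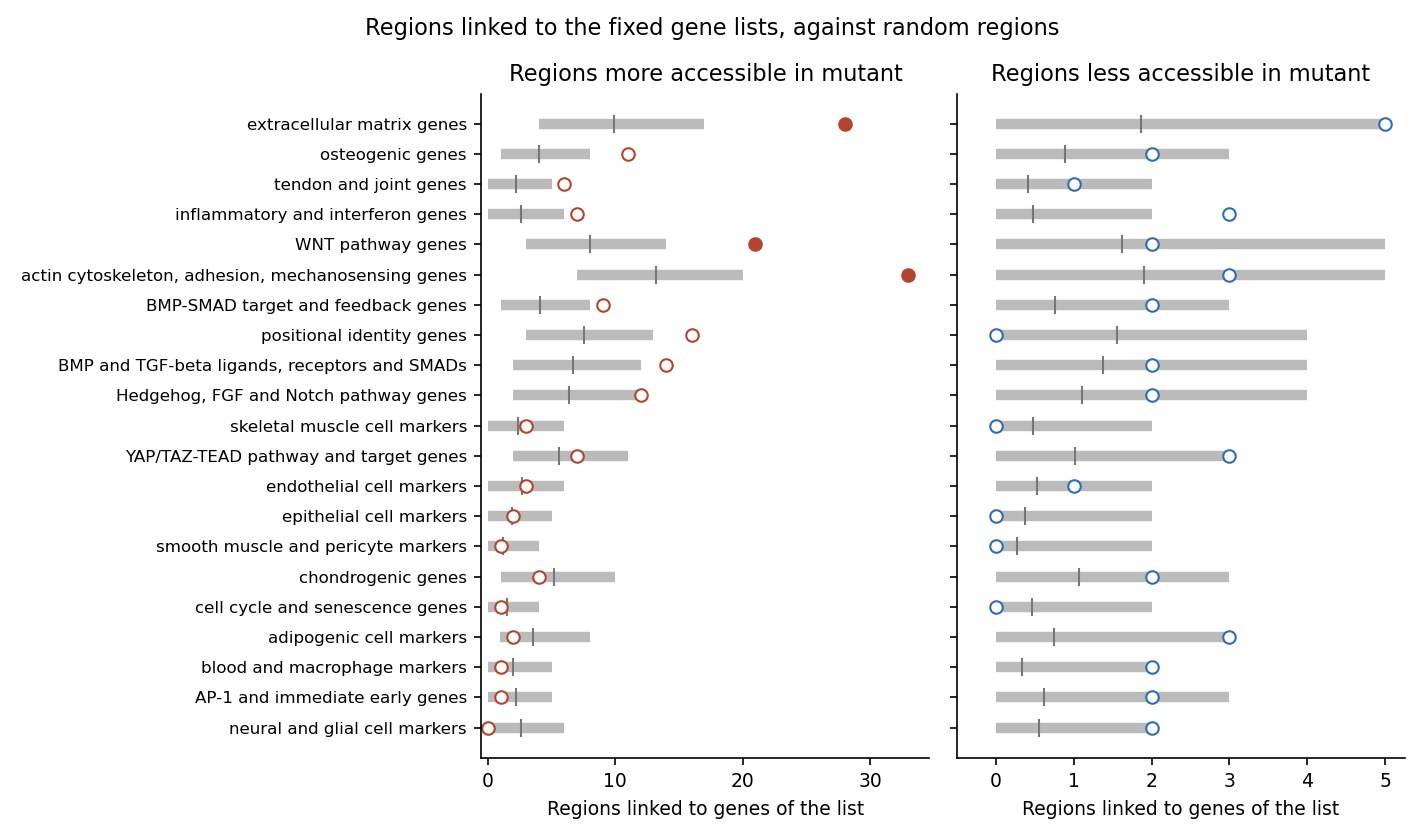
Number of listed regions linked to the genes of each fixed list (circles, x axis) for more accessible (left) and less accessible regions (right), with the mean of 10000 sets of matched random regions (ticks) and the range of 95% of them (grey bars). Filled circles passed an adjusted p of 0.05: the matrix, actin and WNT lists on the left, with 28, 33 and 21 regions, and no list on the right.

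Less accessible regions touched few genes of any list, and no list passed the test against random positions. Matrix genes had 5 regions against 1.87 (adjusted p = 0.26), among them 1 each at Mmp14, a membrane-bound metalloproteinase, Col5a1 and Nid1. Inflammatory genes had 3 against 0.478 (adjusted p = 0.15), 2 at Ptgs2 and 1 at Lif, adipogenic genes 3 against 0.744 (adjusted p = 0.25), 2 at Ebf2 and 1 at Ebf1, and YAP/TAZ-TEAD genes 3 against 1.02 (adjusted p = 0.45), 2 at Amotl1 and 1 at Tead4. Actin and adhesion genes had 3 against 1.90, at Myh9, Itgb3 and Itga4 (adjusted p = 1). BMP-SMAD targets had 2 against 0.756, at Msx1 and Id2 (adjusted p = 0.77), ligands, receptors and SMADs 2 against 1.38, at Bmp6 and Smad3 (adjusted p = 1), and osteogenic genes 2 against 0.884, at Zfp521 and Alpl (adjusted p = 0.87). There were 2 regions each for chondrogenic genes against 1.07 (both at Sox5), WNT genes against 1.62 (Rspo2, Dkk2) and Hedgehog, FGF and Notch genes against 1.10 (Hhip, Spry2; adjusted p = 1 each). AP-1 and immediate early genes had 2 against 0.625, both at Ier3 (adjusted p = 0.60), blood markers 2 against 0.341, at C1qa and Itgam (adjusted p = 0.28), and neural markers 2 against 0.557, at Pax6 and Nes (adjusted p = 0.53). Tendon genes had 1 against 0.411 (Mkx) and endothelial markers 1 against 0.533 (Cdh5; adjusted p = 1 each). Positional genes had 0 against 1.56 (adjusted p = 0.85), and skeletal muscle (0.483), epithelial (0.370), smooth muscle (0.273) and cell cycle genes (0.468) also had 0 (adjusted p = 1 each). Some of these genes had more accessible regions as well. There were 3 at Zfp521, 2 each at Itga4 and Dkk2, and 1 each at Col5a1, Myh9, Smad3, Rspo2, Spry2 and Mkx.

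With the 2 directions set directly against each other, none of the 21 lists passed (two-sided Fisher exact test, lowest adjusted p = 0.32). At an unadjusted Fisher exact p under 0.05 there were 2 lists, both with a larger share of less accessible regions: neural markers (0 and 2 regions, p = 0.025) and adipogenic genes (2 and 3 regions, p = 0.031). Simulations of the test against random positions planted a 3-fold excess in the matrix, actin, WNT and neural lists together. It was found in 11.25% of cases at the size of the less accessible list. At the size of the more accessible list it was found in 75%. Other lists were not covered at that fold. The simulated Fisher exact test gave an unadjusted p under 0.05 in 90.6% of cases where the less accessible share was 3 times the other. That simulation set shares above those of most lists, without adjustment over lists. It did not cover an excess among more accessible regions.

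Among genes with many more accessible regions, Itga11 (chromosome 9, 62677855 to 62783979) had the lowest adjusted p. Its 7 regions compare with 0.257 expected (adjusted p = 0.00026 over 21627 genes) and lie between 62637840 and 62712907, of which 2 are inside the gene and the others 16.0 to 39.7 kb outside it. Dnm3, which encodes a dynamin, had the most regions, 10, all inside its 496 kb span on chromosome 1 (expected 1.05, adjusted p = 0.0019). Dclk1, a doublecortin-like kinase gene, had 7 inside its 297 kb span on chromosome 3 (expected 0.502, adjusted p = 0.0056). Adgrg2, an adhesion receptor gene on X with 4 regions (expected 0.0602, adjusted p = 0.0038), and Ccdc34 with 5 (expected 0.281, adjusted p = 0.0499) also passed; these 2 fall outside the rule for named genes and were chosen after their values were seen. Wwox with 7 regions and Aff3, Robo2, Nav2, Bbs9 and Adamtsl1 with 6 each, in genes of 413 to 1555 kb, did not pass (adjusted p = 0.24 to 1), nor did Tenm4 with 5. Adjusted over the list alone (583 genes of the fixed lists), 3 genes passed: Itga11 (adjusted p = 6.9e-06), Tbx4 (4 regions against 0.156, adjusted p = 0.0063) and Ror2 (5 against 0.424, adjusted p = 0.016). That adjustment was not part of the design. Over all genes the Poisson test did not pass for Tbx4 (adjusted p = 0.067) or Ror2 (adjusted p = 0.14). The 4 regions of Tbx4 lie outside the gene, 7.25 to 68.4 kb from it.

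Among less accessible regions 1 gene passed over all genes, Luzp1 (chromosome 4, 136462609 to 136554725), whose product associates with actin. Its 4 regions lie inside the gene between 136505355 and 136535958 (expected 0.0726, adjusted p = 0.024). Prkcb, a protein kinase C gene, also had 4 regions inside it (expected 0.110, adjusted p = 0.060), and Tns3, Baiap2l1, Arhgef10l and Gsap had 3 each (adjusted p = 0.25 to 1). Tns3, a tensin of focal adhesions, had 3 more accessible regions as well. Adjusted over the list alone, Ier3, an immediate early gene, passed (2 regions against 0.00839, adjusted p = 0.020). Over all genes Ier3 did not pass the Poisson test (adjusted p = 0.25). Linked by the nearest gene end, a choice made after the data were seen, Luzp1 kept 1 region (adjusted p = 1), and Dnm3 with 5 regions (adjusted p = 0.11) and Ccdc34 (adjusted p = 0.062) did not pass.

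**Figure D4:**
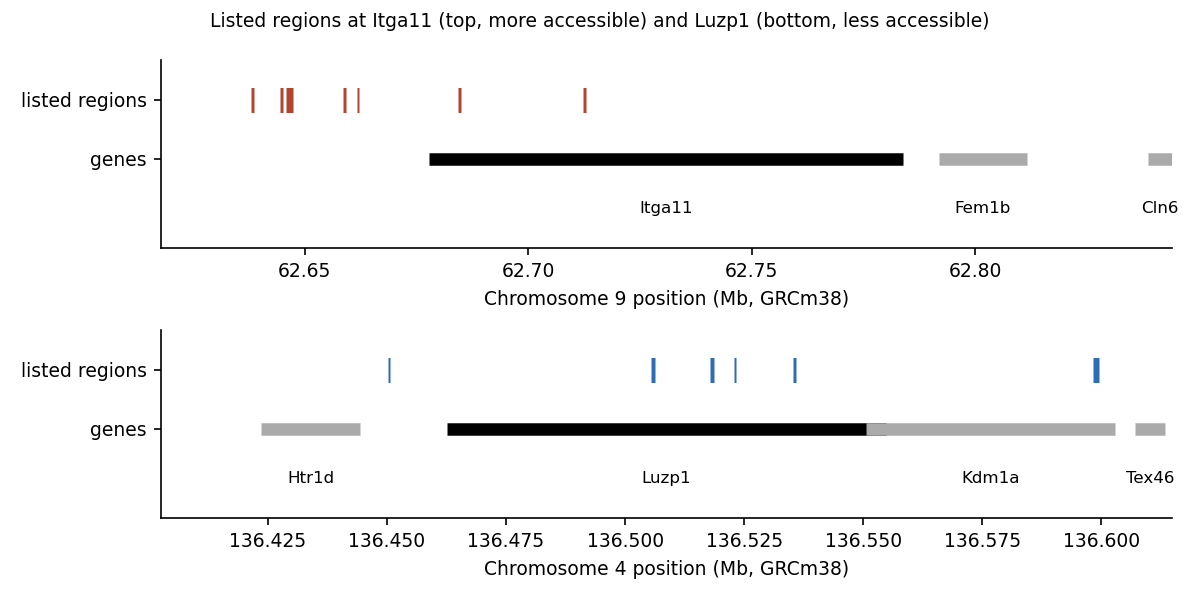
Listed regions (coloured bars, drawn to scale) and protein-coding genes (thick lines) along chromosome 9 around Itga11, top, and chromosome 4 around Luzp1, bottom; x axes are positions in Mb on GRCm38. Of the 7 more accessible regions (red) linked to Itga11, 5 lie beyond its left end and 2 inside it, and the 4 less accessible regions (blue) linked to Luzp1 lie inside it.

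Regions of the same direction lay close together. In the more accessible list 345 regions (11.6%) had a neighbour of the list within 10 kb, against a mean of 79.9 and a highest count of 127 over 500 random sets. In the less accessible list 30 (5.40%) did, against 3.21 and 12. More accessible regions were linked to 1581 genes and less accessible regions to 435, with 80 genes in both. At least 3 regions were linked to 156 genes in the more accessible list (random mean 74.9, highest 102) and to 6 genes in the less accessible list (random mean 0.445, highest 4). The tests of genes and lists treat regions as independent, so their p-values are too small where neighbouring regions are listed together.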

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

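No paired analysis was possible because the lists hold no value per library; for the same reason leaving out each replicate, a replicate block and a stricter threshold were not run, and the motif and GC alternatives were not run for want of sequence. Linking by the nearest gene end was chosen after the data were seen. Of 381 values under alternatives 31 reversed, none with an adjusted p under 0.05; the cause was not tested. The share of more accessible regions was 84.1% with regions within 1 kb merged and 84.2% on autosomes. Within 5 kb of each other, rather than overlapping, lay 2 regions of the less accessible list. Near gene ends the odds ratio was 0.401 at 500 bp (adjusted p = 0.11). Inside genes it became 1.04 at 2.5 kb, and between genes 1.35 with all annotated genes (adjusted p = 0.0023). The number of lists past the threshold was 7 with links at any distance and 0 with each gene counted once. Genes with at least 3 more accessible regions numbered 264 with links at any distance and 91 by the nearest gene end. Without its leading gene, chosen after the data were seen, the fold was 2.03 for actin, 2.56 for matrix and 2.11 for WNT genes.

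The other reversals were folds of lists over random, or odds ratios of more to less accessible, that crossed 1. With links within 10 kb the folds for more accessible regions were 0.620 for skeletal muscle, 0.654 for endothelial and 1.19 for smooth muscle markers, and for less accessible regions 0 for tendon and 0 for endothelial genes. The odds ratios were 0.788 for BMP and TGF-beta ligands, 1.06 for Hedgehog, FGF and Notch and 0.563 for skeletal muscle genes. With links at any distance the folds were 1.45 for chondrogenic, 1.39 for AP-1, 2.02 for adipogenic and 1.51 for cell cycle genes, and 1.50 for cell cycle genes among less accessible regions. The odds ratios were 0.766 for BMP and TGF-beta ligands, 1.24 for osteogenic, 1.29 for matrix and 1.06 for endothelial genes. With all annotated genes the odds ratios were 1.31 for BMP-SMAD targets, 0.713 for BMP and TGF-beta ligands, 1.69 for tendon and 0.939 for skeletal muscle genes. With each gene counted once the folds were 0.874 for endothelial and 0.652 for epithelial markers, and 0.986 for chondrogenic genes among less accessible regions, with odds ratios of 0.984 for actin and 1.01 for matrix genes. By the nearest gene end the folds for chondrogenic genes were 1.20 and, among less accessible regions, 0, with odds ratios of 0.863 for BMP and TGF-beta ligands and 2.07 for chondrogenic genes.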

Other observations

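Apart from the planned count of each gene once, the tests in this part were chosen after the results they bear on were seen. Among 257 gene families formed by the stem of the symbol, 2 had more regions that gained accessibility than random positions (Poisson, Benjamini-Hochberg over 514 tests). Integrin alpha genes had 13 against 2.37 (5.48-fold, adjusted p = 0.00046), at Itga11, Itga8, Itga4 and Itga9. Itga11 held 7 of these, and without it the family did not pass (6 regions against 2.11, 2.84-fold, adjusted p = 1). CXC chemokine genes had 8 against 0.863 (9.27-fold, adjusted p = 0.00091), at Cxcl12, Cxcl14, Cxcl15, Cxcl1 and Cxcl5. The family passed without Cxcl14, which shared the highest count, 2 regions, with Cxcl12 and Cxcl15 (8.09-fold, adjusted p = 0.032). Leaving out Cxcl12 or Cxcl15 was not tested, nor was whether several of the 8 regions lie at a single locus. The gene clusters of olfactory receptors (4 regions against 26.6, adjusted p = 7.2e-05) and vomeronasal receptors (0 against 15.5, adjusted p = 1e-04) had fewer. No family passed among less accessible regions. Of the positional identity list, the 36 genes other than Hox genes had 16 more accessible regions against 6.68, at Tbx4, Tbx15, Tbx18, Prrx1, Prrx2, Twist2, Hand2, Lmx1b, Pitx1 and Meis2.

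The matrix, actin and WNT lists together had 82 more accessible regions against 31.1 expected (2.64-fold, 2.10 to 3.28). They were pooled because each had passed on these same regions, so this fold is no further support. Its interval also treats regions as independent. With each gene counted once, actin genes were near random (12 genes against 9.98, 1.20-fold, adjusted p = 1), consistent with a few loci such as Itga11 carrying the excess, while for matrix genes (1.85-fold, adjusted p = 0.26) and WNT genes (1.74-fold, adjusted p = 0.39) this stays open, as the folds lie above 1 without passing. Random positions also include chromatin closed in fibroblasts, which may inflate such folds: olfactory and vomeronasal receptor genes were below random among less accessible regions too (0.195-fold, 0.0402 to 0.569). Whether fibroblast genes hold more open chromatin in either genotype stays open. Less accessible regions gave 1.85-fold for the same lists (0.889 to 3.41), and the odds ratio of the directions was 1.55 (0.796 to 3.38, Fisher exact p = 0.25). This odds ratio can lean towards more accessible regions, because the lists were chosen for passing in that direction. For matrix genes alone the folds were 2.83 among more and 2.67 among less accessible regions, with an odds ratio of 0.97. For actin genes they were 2.51 and 1.58 (odds ratio 1.81), and for WNT genes 2.62 and 1.24 (odds ratio 1.62). An effect of the mutant receptor on these genes therefore cannot be told apart from chromatin that is open in either genotype.

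More accessible regions lay away from gene ends. Coordinates of another build are argued against, since the unshifted share within 1 kb of an end, 1.08%, was below that under each of 10 shifts (1.72 to 3.24%). The share of less accessible regions, 3.60%, was also below that under each shift (3.96 to 5.40%). A low share beside gene ends, compared with nearby positions, was therefore not particular to more accessible regions. Chromosomes of different gene density do not account for the whole difference in distance from less accessible regions, as 0.302 of it on the log10 scale was left within chromosomes (permutation p = 0.0001, the smallest it can give). An even gain of signal over all open regions in the mutant libraries could not be weighed, because the share near gene ends among all tested peaks is not analysed here, and the less accessible regions, with 3.60%, are the only other open regions at hand. An effect of genotype on distal elements and such a gain cannot be told apart.

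Limb regulators such as Tbx4 and Prrx1 were linked to more accessible regions, while 5 genes known from mesothelium, Msln, Upk3b, Bnc1, Krt19 and Cst6, had 6 less accessible regions against 0.0677 expected. These 5 genes were picked because they were seen, so their count tests nothing. Fewer mesothelial cells in the mutant cultures may be a candidate source, but 18 further markers had 0 less accessible regions against 0.504 expected, too few to decide; of all 23 markers, 4 also stand in a fixed list, and which of them fibroblasts express was not analysed here. Cultures made from different parts of the embryo are another candidate source, and Hox genes, which would mark this, had 0 regions against 0.873 expected (upper bound 3.69), which decides nothing either. Neither can be told apart from an effect of genotype.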
